A study of Mus musculus with 237 samples.

How the data were processed

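Cells of mouse embryonic kidneys were freed by proteolytic digestion, enriched by flow sorting and captured singly in a microfluidic device, as the labels state. Each sample is 1 cell. The authors deposited a single table of RPKM, which scales reads to transcript length and to the mapped reads of each cell, for 36186 gene entries in 237 cells, made by aligning reads to mm10 with TopHat. The version, the gene models and the counting rule are not stated. Of the gene entries, 18447 are at 0 in every cell, and 94 symbols stand on more than 1 entry and were kept apart by gene ID. Gene IDs were matched to the RefSeq annotation of GRCm38.p6 for 32916 entries, of which 58.5% had the same start and 99.98% the same chromosome, so positions printed are those of the deposited table. No counts are given, so read depth per cell is unknown. Ratios between low values did not fall on steps that would give it (a median of 13.3% in the 3 fullest bins of 0.02 log2 units over 189 pairs of cells), and the number of genes at 1 RPKM or more stands in for depth. The sum of RPKM per cell had medians of 416943, 410875, 388516, 429456 and 405780 in E18.5 cap, interstitium, E18.5 mutant, E13.5 cap and E13.5 mutant cells. No 2 cells had identical values (highest correlation 0.809, median 0.536).

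Cells were grouped by source name, cell type label, genotype and age. One cell whose source name says cap mesenchyme while its cell type label says interstitium entered no comparison. All other cells were kept. Because no label names an embryo, cells are not independent animals: each group counts as 1 sample, and no p-value, standard error or count of changed genes was computed. No paired analysis was possible because no label pairs a cell of 1 group with a cell of another. The titles carry a pool number. Pool 2 holds the 74 E18.5 cap cells and 22 interstitium cells, pool 3 holds the other 49 interstitium cells and the 18 cap and 29 mutant cells of E13.5, and pool 4 holds the 44 E18.5 mutant cells and the cell left out. The E13.5 comparison therefore lies within 1 pool, and interstitium minus cap was also made within pool 2. Pool and group cannot be told apart in comparisons with E18.5 mutant cells or between ages. Values were taken as log2(RPKM + 1) and averaged over the cells of a group, with the SD between cells. A gene was called detected in a cell at 1 RPKM or more, and shares carry 95% exact Clopper-Pearson intervals, which cover counting error only. The sex of each cell was read from Xist and the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d. No doublet caller was used.

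The comparisons, gene lists, naming rule and a set of alternatives were chosen before the data were examined. The text names genes from among Pax2, members of the fixed lists, and for each comparison the 10 genes with the largest positive and the 10 with the largest negative difference. These 10 were taken among genes at 1 RPKM or more in 50% of the cells of the higher group, without Gm and Rik gene models, mitochondrially encoded, ribosomal protein and haemoglobin genes. Any other gene, such as LOC100503946 and the imprinted genes outside these lists, was chosen after its values were seen. The 31 lists hold 325 distinct genes, 3 of which match no entry: nephron progenitor, committing nephron, proximal tubule, loop and distal tubule, podocyte, epithelial adhesion, nephrogenic interstitium, stromal and fibroblast, mural and smooth muscle, ureteric epithelium, endothelium, immune, erythroid, neural and glial, skeletal muscle and cartilage, S phase, G2 and M phase, immediate early and stress, p53 targets and apoptosis, Wnt targets, Notch pathway, FGF response, hedgehog response, retinoic acid pathway, extracellular matrix, epithelial to mesenchymal transcription factors, Pax and Hox network (with members such as Eya1, Six2, Sall1 and Wt1), glycolysis, oxidative phosphorylation, housekeeping and sex linked. A list of 23 imprinted genes, and the 12 of them that had not been seen among the leading genes, were added after the data were seen. The score of a list is the mean over its members in each cell. A list was also described by the median difference of its members and its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. Percentiles and random medians refer to this member median, also where only the score is printed beside them.

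The lineage index used the 100 genes with the largest difference in each direction between odd-numbered interstitium and cap cells at E18.5, among genes detected in 50% of the cells of the higher group. It is the mean over interstitium genes minus the mean over cap genes, scaled on the even-numbered cells. Clusters were made from log2(RPKM + 1) of the 1500 most variable genes, 15 principal components and 10 neighbours with Leiden at resolution 1. A cluster took the class with the most fixed markers that were higher by 1 log2 unit in the cluster and detected in 50% of its cells. It needed at least 3 such markers, and no name was given where the pseudogene LOC100503946 led the cluster. In the main clustering the text also withholds the name where the 10 leading genes held more markers of another class, as in cluster 8. That check was not applied in the other cluster settings. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.

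Alternatives were pseudocounts of 0.1 and 10, rescaling every cell to the same RPKM sum, median-ratio scaling over genes detected in 80% of cells, medians over cells, the log2 ratio of mean RPKM, interstitium pools 2 and 3 alone, leaving out cells under 2000 genes, detection above 0 or at 5 RPKM, list members detected in 10% of either group, progenitor-like cells alone, 50 or 200 index genes, the odd and even cells swapped, list or cell cycle and immediate early genes left out of the index, and other cluster settings. Added after the data were seen were leaving out cells at 20000 RPKM or more for LOC100503946, cells with 3000 to 5000 genes, sex-linked genes out of the index, and list members out of the clustering. The steps were tested on simulated data with 10396 genes, 200 of them changed 8-fold. Raised genes had a median difference of 2.41, lowered genes of -1.75 and unchanged genes of -0.01. Of the changed genes, 100% had the right sign, and cells mixed midway had a median index of 0.491. Because the index is a difference of means, a value near midway for mixed cells is close to given and is no test of it. The simulated unchanged genes had no shift like the -0.40 between mutant and cap cells at E18.5. The effect of such a shift was therefore not tested.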

Results

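Single cells of the embryonic mouse kidney were profiled by RNA sequencing after sorting and microfluidic capture. The labels place 236 cells in 5 groups. At E18.5 (the embryonic day) there were 74 wild-type cells of the cap mesenchyme and its descendants, 71 wild-type interstitium cells and 44 Pax2 mutant cap cells. At E13.5 there were 18 wild-type cap cells and 29 Pax2 mutant cap cells. The cap mesenchyme holds the progenitors of the nephron, and the interstitium is the stroma around it. Pax2 encodes a transcription factor of the nephron lineage, and the series asks how Pax2 relates to the division between these lineages. A further cell, whose source name and cell type label name different lineages, entered no comparison.

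No label names the embryo a cell came from, so each group counts as 1 sample and no test between groups was made. All SDs describe the spread between cells, and shares carry exact 95% Clopper-Pearson intervals that cover counting error only. Each group has its own date in its titles, so group and day cannot be told apart. Most cells of each group also showed the transcripts of a single sex. Xist, the RNA of the inactive X chromosome, was at 1 RPKM or more without a Y-linked transcript in 67 of 74 E18.5 cap, 42 of 44 E18.5 mutant and 27 of 29 E13.5 mutant cells. Y-linked transcripts without Xist were found in 70 of 71 interstitium and 17 of 18 E13.5 cap cells. Both kinds were found in 6 E18.5 cap, 1 interstitium, 2 E18.5 mutant and 2 E13.5 mutant cells. In 1 of these E13.5 mutant cells both were high, with Xist at 109.2 RPKM and a Y-linked gene at 30.6. Sex therefore differed in the comparisons of interstitium with cap, of mutant with interstitium, of mutant with cap at E13.5, and of cap cells between ages.

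The deposited table gives RPKM and no counts, so the read depth of each cell is unknown. The median number of genes at 1 RPKM or more was 5210.5 in E18.5 cap cells (range 1656 to 7215) and 5178 in interstitium cells (3085 to 7196). It was lower in E18.5 mutant cells, at 3643 (2284 to 5109). At E13.5 it was 5566 in cap cells (4355 to 6661) and 4560 in mutant cells (1849 to 5858). The median difference over all genes detected in 10% of the cells of either group was -0.40 log2 units between mutant and cap cells at E18.5 as deposited. It was -0.50 after rescaling every cell to the same RPKM sum and -0.32 after median-ratio scaling. The same 3 values were -0.41, -0.54 and -0.31 for mutant minus interstitium cells, -0.45, -0.59 and -0.28 for mutant minus cap cells at E13.5, and 0.01, 0.04 and -0.03 for interstitium minus cap cells. The percentile of a list among random lists matched on expression takes this shift into account, while a list score does not. LOC100503946, annotated as a pseudogene of the mitochondrial ATP synthase F0 subunit 6 (chromosome 1, 24613971 to 24614812), reached 20000 RPKM or more in 20 of 74 E18.5 cap, 9 of 71 interstitium, 4 of 44 E18.5 mutant, 1 of 18 E13.5 cap and 8 of 29 E13.5 mutant cells.

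**Figure D1:**
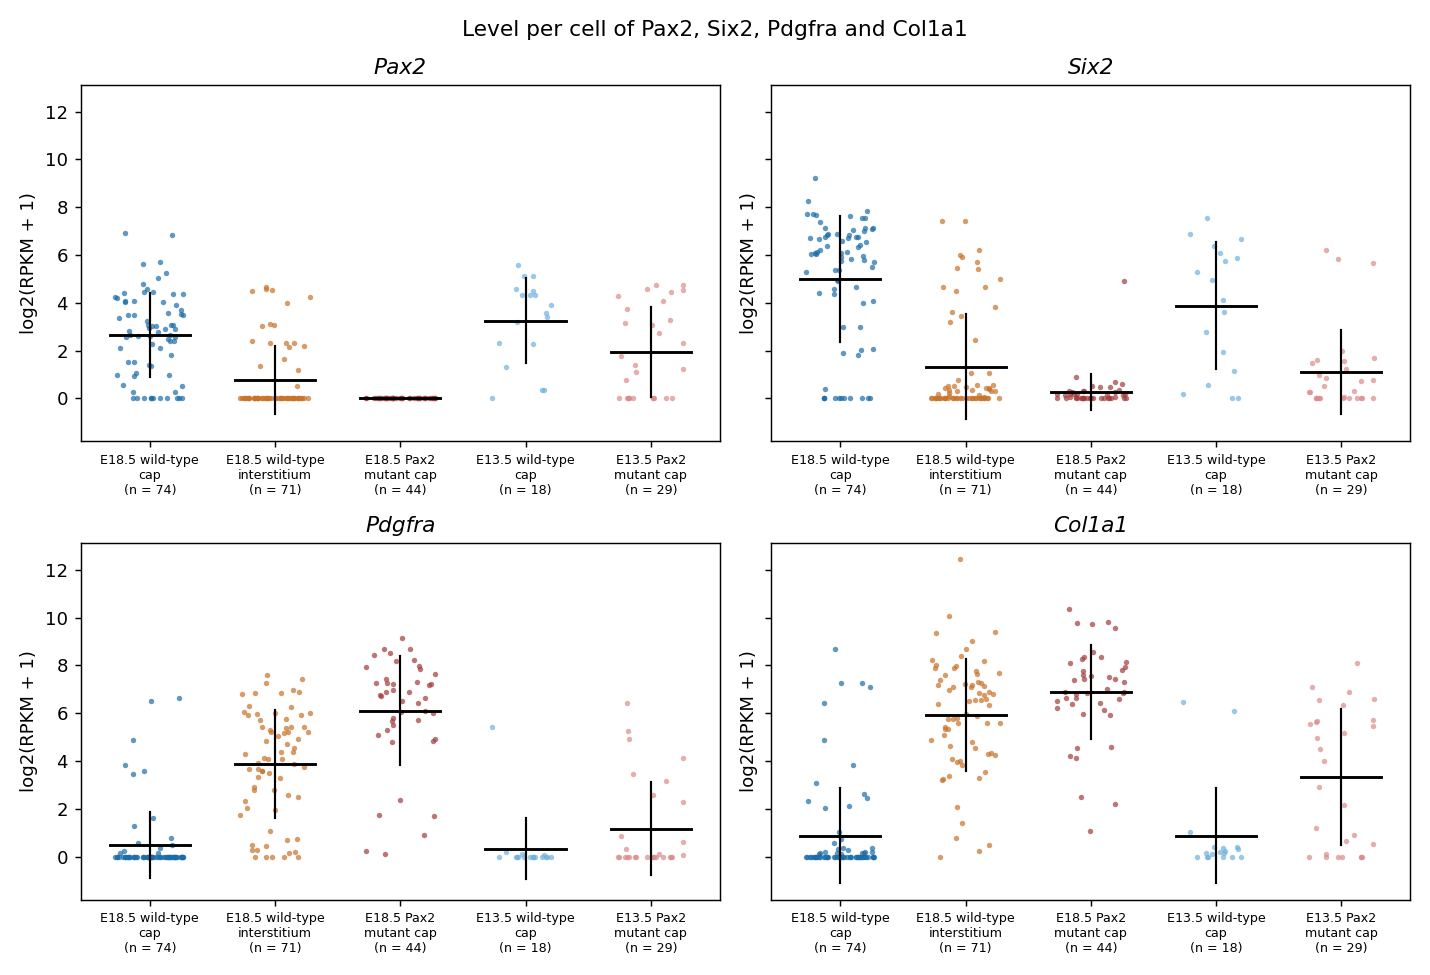
Level of Pax2, Six2, Pdgfra and Col1a1 in each cell (vertical axes, log2(RPKM + 1)) by group (horizontal axes), with a panel for each gene. Points are cells and lines are the mean with the SD between cells. All 44 E18.5 mutant cells are at 0 for Pax2.

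Pax2 transcripts were found in most wild-type cap cells, in a minority of interstitium cells and in none of the 44 E18.5 mutant cells. Pax2 (gene ID 18504, mm10 chromosome 19, 44757394 to 44837869) had a mean log2(RPKM + 1) of 2.64 ± 1.76 in E18.5 cap cells, where 56 of 74 cells (75.7%, 64.3 to 84.9) reached 1 RPKM. In interstitium cells the mean was 0.76 ± 1.42, with 18 of 71 cells (25.4%, 15.8 to 37.1). Nearly all of these 18 also had Six2 at 1 RPKM. They comprised all 11 interstitium cells of the clusters classed below as nephron progenitor-like and 7 of the other 60. The share is therefore mostly that of cells with a progenitor or mixed profile in this group. All 44 E18.5 mutant cells were listed at 0, which allows a share of up to 8.04%. At E13.5 the mean was 3.26 ± 1.76 in cap cells, 15 of 18 of which reached 1 RPKM (83.3%, 58.6 to 96.4). In E13.5 cells labelled mutant it was 1.93 ± 1.88, with 17 of 29 cells (58.6%, 38.9 to 76.5), a difference of -1.33 log2 units that is within 1 SD. The labels do not say which part of Pax2 is altered, whether the allele is the same at both ages, or whether E13.5 mutant cells carry 1 altered copy or both, and a value per gene cannot show whether a transcript is intact. E13.5 mutant values therefore describe cells labelled mutant, 17 of 29 with Pax2 transcript, and comparisons with E18.5 mutant cells carry this difference. The size of the differences depends on the pseudocount: mutant minus cap at E18.5 was -2.64 with 1, -5.20 with 0.1 and -0.84 with 10.

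The wild-type lineages at E18.5 were compared to see which transcripts part them. Interstitium cells held more of the stromal and matrix transcripts and fewer of the nephron progenitor transcripts than cap cells. Of 14 stromal and fibroblast genes, 10 were higher by 1 log2 unit or more and none was lower, and the mean score of the list was 2.83 ± 1.18 against 0.51 ± 0.83. The collagen genes Col1a1 (ID 12842, chromosome 11, 94936270 to 94951856) and Col3a1 were higher by 5.05 and 5.01. The receptor gene Pdgfra (ID 18595, chromosome 5, 75152291 to 75198204) was higher by 3.42, at 3.88 ± 2.25 against 0.47 ± 1.38. Of 12 nephrogenic interstitium genes, 8 were higher and 1, Rspo3, was lower (-1.25). The homeobox gene Meis1 (ID 17268, chromosome 11, 18880428 to 19018969) was higher by 4.93 and reached 1 RPKM in 69 of 71 interstitium cells and 36 of 74 cap cells. Foxd1 (ID 15229, chromosome 13, 98354245 to 98356705), a transcription factor of the stromal progenitors that is also named in the titles of the interstitium cells, was higher by 1.13, at 2.19 ± 2.07 against 1.06 ± 1.505. Of 14 extracellular matrix genes, 10 were higher and none was lower, with Fn1 higher by 2.93 and Col5a2 by 2.95.

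Nephron progenitor genes showed the opposite direction, with 8 of 12 lower by 1 log2 unit or more in interstitium cells and none higher. Six2 (ID 20472, chromosome 17, 85684268 to 85688254), which keeps nephron progenitors undifferentiated, had a mean of 1.33 ± 2.19 in interstitium and 5.01 ± 2.65 in cap cells, a difference of -3.68. Crym (-4.15) and the Six2 partner Eya1 (-3.26) were among the 10 named genes with the lowest values, with Enpp2 (-3.68), Six3 (-3.46), Vcan (-3.29), Nell1 (-2.94), Slc12a2 (-2.89) and Robo2 (-2.87). Gdnf, the ligand that directs the ureteric bud, was 0.78 higher in interstitium cells. In the list of Pax and Hox network genes, which also holds Eya1 and Six2, 8 of 14 were lower and none was higher, with Pax8 at -1.89 and Hoxd10 at -1.83. The genes with the largest positive differences were Penk (5.61), Ifitm3 (5.38), Ccnd2 (5.28), Anxa2 (5.26), Col1a1, Col3a1, Meis1, Sfrp1 (4.83), Plagl1 (4.75) and Cnn2 (4.69). Cell cycle scores were alike, differing by 0.01 for the S phase list and by -0.11 for the G2 and M phase list (-0.33 to 0.86 and -0.38 to 0.43 over the alternatives), while Ccnd1 was higher by 3.26 in interstitium cells.

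Among 10000 random lists of the same size and like expression, the median of the members was at percentile 100 for the stromal (1.88), nephrogenic interstitium (1.35) and matrix (1.42) lists, and at percentile 0 for the nephron progenitor (-1.62) and Pax and Hox network (-1.32) lists. The random lists had medians between -0.01 and 0.03. Lists with smaller score differences were oxidative phosphorylation (0.89, percentile 99.5), the retinoic acid pathway (0.67, percentile 96.3, with Dhrs3 higher by 3.33 and Rdh10 at -1.48), immediate early and stress genes (0.59, percentile 99.6, with Fos higher by 2.59) and hedgehog response (0.48, percentile 99.5, with Boc higher by 2.03). These percentiles describe the libraries at hand and are not tests between animals. The oxidative phosphorylation difference was 0.18 without cells at 20000 RPKM or more for the ATP synthase pseudogene, and the retinoic acid difference 0.43. The titles place 22 of the interstitium cells in the pool of the cap cells. With these cells alone, the differences from cap cells were 2.49 for the stromal list, 1.46 for nephrogenic interstitium, 1.53 for matrix, -1.53 for the progenitor list and 0.53 for oxidative phosphorylation. Glycolysis (-0.40), S phase (-0.33) and FGF response (-0.05) stood lower there than in all interstitium cells. The progenitor score difference of -1.51 became 0.54 when only cells of the progenitor-like clusters were compared (11 interstitium and 52 cap cells). These clusters were picked on members of the same list, so this value does not speak to the difference between the lineages.

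The E18.5 mutant cells were compared with wild-type cap cells to see what cells of the same sort hold when Pax2 is altered. Mutant cells held few nephron progenitor transcripts and high levels of stromal and matrix transcripts. Of 12 nephron progenitor genes, 9 were lower by 1 log2 unit or more and none was higher, and the list score was 0.45 ± 0.47 against 2.99 ± 1.195. Six2 was at 0.27 ± 0.75 in mutant cells (-4.74) and reached 1 RPKM in 1 of 44 cells (2.27%, 0.0575 to 12.02), against 62 of 74 cap cells (83.8%, 73.4 to 91.3). Values above 0 but under 1 RPKM were common for this gene. Counting any value above 0 gave 56.8% of E18.5 mutant, 54.9% of interstitium and 85.1% of cap cells. Crym (-5.39), Eya1 (-4.33), Sall1 (-3.41), Cited1 (-3.13), Osr1 (-2.43) and Gdnf (-1.93) were lower as well, and no mutant cell had a Cited1 value above 0. In the Pax and Hox network list, 9 of 14 genes were lower and none was higher, including Pax8 (-2.47), which was listed at 0 in all 44 cells, and Wt1 (-2.41), at 3.54 ± 3.35 against 5.95 ± 2.34.

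Stromal and fibroblast genes were higher in mutant cells for 12 of 14 members and lower for none, with a score of 3.57 ± 1.23 against 0.51 ± 0.83. Col1a1 (mean 6.88 ± 1.97) and Col3a1 (5.71 higher) were found in all 44 mutant cells, against 14 and 12 of 74 cap cells. Pdgfra was found in 41 of 44 mutant cells at a mean of 6.11 ± 2.29. Of the 12 nephrogenic interstitium genes, 7 were higher, including Meis1 (4.81), Crabp1 (4.46), Dlk1 (3.50), Fat4 (2.58), Ntn1 (2.47) and Foxd1 (1.53). The retinoic acid synthesising enzyme gene Aldh1a2 was lower (-1.98). Foxd1 was detected in 27 of 44 mutant and 25 of 74 cap cells. Of 14 matrix genes, 10 were higher, among them the type VI collagens Col6a1 (4.66) and Col6a3 (4.26) and Fn1 (2.97), and 1 was lower, Tnc (-1.53). Among the 10 genes with the largest positive differences were Penk (6.22), Col1a1, Col3a1, Pdgfra (5.64), Col1a2 (5.53), Sparcl1 (5.53), Plagl1 (5.44), Postn (5.34) and Plac9a (5.25), whose reads cannot be told apart from those of the near-identical Plac9b. The medians of the stromal (2.52), nephrogenic interstitium (1.43) and matrix (2.27) lists were at percentile 100, where random lists had medians of -0.40, -0.66 and -0.59. The progenitor list median of -2.68 was at percentile 0, against a random median of -0.53.

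Cell cycle transcripts were low in E18.5 mutant cells. Of 12 S phase genes and of 12 G2 and M phase genes, 11 each were lower than in cap cells and none was higher, with scores of 0.93 ± 0.75 against 3.69 ± 1.96 and 0.79 ± 1.12 against 3.89 ± 2.52. Their member medians of -2.86 and -3.21 were at percentile 0, against -0.57 and -0.70 in random lists. Top2a, which unlinks replicated DNA, was found in 2 of 44 mutant and 63 of 74 cap cells (-5.22), Mki67 in 5 and 48 (-3.11) and Rrm2 in 4 and 52 (-4.21). The S phase gene Mcm6 was lower as well (-2.91), and Cdc20, found in every cell of every group, differed by -0.67. The other named genes with the most negative differences were Enc1 (-7.02), Fam60a (-5.64), Fxyd6 (-5.61), Phgdh (-5.24), Kpna2 (-4.92), Cd24a (-4.91) and Hmgb2 (-4.84). Genes induced by FGF signalling were lower for 6 of 10 members and higher for none (score -1.47, percentile 0.07), with Etv5 at -3.42 and Spry4 at -2.15. Dusp6 was found in 5 of 44 mutant and 59 of 74 cap cells (-3.29), while the log2 ratio of its group mean RPKM was 0.68 higher in the mutant because of high values in those few cells. Immediate early and stress genes were higher for 5 of 12 members (score 1.02 higher, percentile 100), including Btg2 (3.57), Fos (3.34), Jun (2.43) and Egr1 (1.49), and lower for 1. Glycolysis genes were lower for 9 of 12 members (score -1.72, percentile 0.05), with Pgk1 at -3.32 and Gapdh at -2.92. Oxidative phosphorylation genes were lower for 8 of 12 (score -1.19, percentile 1.81), with Atp5b at -1.63, and housekeeping genes differed by -0.86 (percentile 30.7).

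The lower number of genes per mutant cell bears on each of these values. In 33 mutant and 26 cap cells with 3000 to 5000 genes each, an alternative added after the data were seen, the score differences were 2.89 for the stromal list, -1.77 for the progenitor list, -1.38 for S phase, -1.40 for G2 and M phase, -1.11 for the Pax and Hox network, -0.95 for FGF response and -0.69 for glycolysis, while oxidative phosphorylation (0.07) and housekeeping genes (0.07) no longer differed in the direction seen in all cells. As ratios of group mean RPKM, glycolysis stood at -0.99, oxidative phosphorylation at -0.33 and housekeeping genes at -0.37. The mutant and cap cells compared at E18.5 were of the same sex. The 26 matched cap cells may differ from the other cap cells in more than gene number. They include cells without Six2 and with Pdgfra, such as a cell with 4071 genes, Six2 at 0 and Pdgfra at 6.62. The smaller differences in matched cells can therefore not be put down to gene number alone.

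Mutant cells were also set against wild-type interstitium cells, since both held stromal transcripts. Stromal genes were higher in the mutant for 3 of 14 members and lower for none, with a score difference of 0.74 (percentile 100), and Pdgfra was higher by 2.23 and Postn by 1.55. Nephrogenic interstitium genes went both ways: 4 of 12 were higher, including Crabp1 (3.21), Dlk1 (2.66), Rspo3 (2.58) and Fat4 (1.13), and 2 were lower, including Aldh1a2 (-2.52). The score difference was 0.29 and the median of the members -0.16, while the score difference was 0.73 after median-ratio scaling, 0.51 without pseudogene-high cells and 0.49 in cells with 3000 to 5000 genes. Meis1 (-0.12) and Foxd1 (0.40) were close between these groups. All 12 S phase genes and 11 of 12 G2 and M phase genes were lower in the mutant, with score differences of -2.77 and -2.99. Their member medians of -2.92 and -3.165 were at percentile 0, against random medians of -0.62 and -0.67. In the FGF list 5 of 10 genes were lower and none was higher (score -1.58, percentile 0). Glycolysis (-1.77, percentile 0.21) and oxidative phosphorylation (-2.08, percentile 0) scores were lower too. Housekeeping genes, at -1.11 (percentile 51.3), differed no more than genes of like expression. Progenitor genes were lower for 6 of 12 members (score -1.04, percentile 0.08), with Sall1 at -2.09 and Gdnf at -2.71. In 33 mutant and 35 interstitium cells with 3000 to 5000 genes these differences were smaller, at -1.77 for S phase, -1.75 for G2 and M phase, -1.27 for FGF response, -0.9975 for glycolysis, -1.18 for oxidative phosphorylation and -0.39 for the progenitor list. As ratios of group mean RPKM, glycolysis stood at -0.79 and oxidative phosphorylation at -0.68. Of the first 5 lists in matched cells, only FGF response differed by more than the SD of both groups. The stromal difference was 0.85 in these cells, and 1.14 in all cells after median-ratio scaling. The interstitium group was mixed, with 11 cells in progenitor-like clusters, which were picked on members of the progenitor list. The progenitor score was 4.106 in these 11 and 1.004 in the other 60 interstitium cells, against 0.45 in mutant cells. The stromal score was 1.372 and 3.095, against 3.571 in mutant cells. Set against the 60 cells, the progenitor and stromal differences are thus smaller than in the whole group. Beyond Xist (5.24), which follows sex, the named genes with the largest positive differences were the Wnt antagonist Sfrp4 (4.25), Meg3 (3.72), Txnip (3.71), Sparcl1 (3.54), Rian (3.38), Matn2 (3.21), Crabp1, Figf (2.997) and BC028528 (2.95). Sfrp4 was found in 27 of 44 mutant, 2 of 71 interstitium and 1 of 74 cap cells. The most negative were Fam60a (-5.29), Slc25a5 (-5.05), Hmgb2 (-4.76), Peg12 (-4.63), Enc1 (-4.60), Hmgb3 (-4.52), Kpna2 (-4.47), Nme1 (-4.42), Top2a (-4.41) and Uhrf1 (-4.39).

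**Figure D2:**
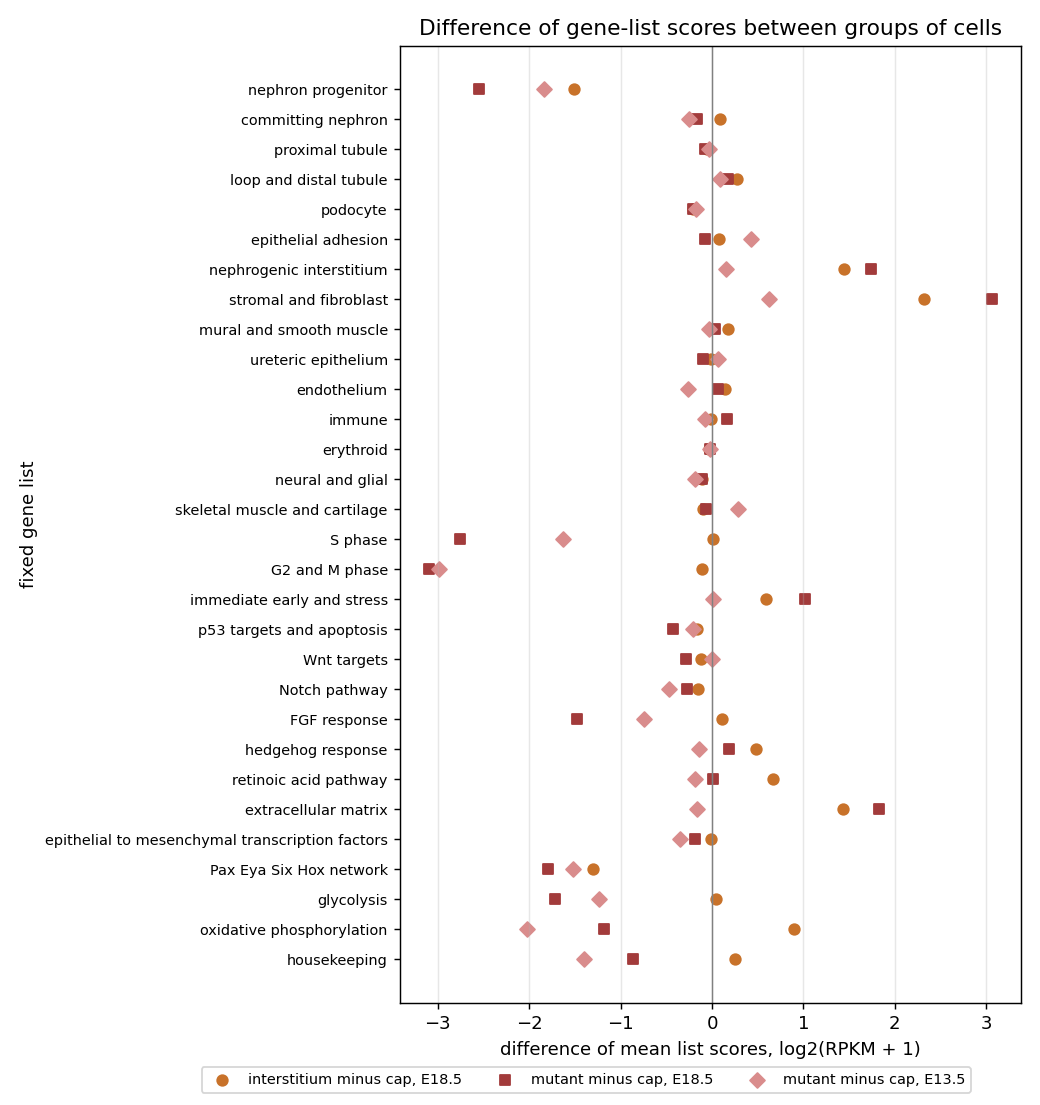
Difference between group means of the score of each fixed gene list (horizontal axis, log2(RPKM + 1)); the sex-linked list is not drawn. Points are the 3 comparisons; the stromal and fibroblast list stands at 2.32 for interstitium minus cap, 3.07 for mutant minus cap at E18.5 and 0.62 for mutant minus cap at E13.5.

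At E13.5 the mutant was compared with cap cells to see which of these differences are present at the earlier age. Nephron progenitor genes were lower in the mutant for 8 of 12 members and higher for none, with a score of 0.78 ± 0.69 against 2.62 ± 1.19 (percentile 0, member median -1.69 against -0.44 in random lists). Six2 was at 1.10 ± 1.78 against 3.88 ± 2.65 (-2.77) and reached 1 RPKM in 9 of 29 mutant and 14 of 18 cap cells. Counting any value above 0 gave 62.1% and 88.9%. Sall1, another regulator of the progenitors, had the most negative difference of the named genes (-4.95), and Crym (-3.16), Eya1 (-2.71) and Gdnf (-2.04) were lower as well. In the Pax and Hox network list 7 of 14 genes were lower and none was higher (score -1.52), with Wt1 at -2.46 and Pax8 at -2.17.

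Stromal transcripts were higher in part of the E13.5 mutant cells. Of 14 stromal genes, 3 were higher by 1 log2 unit or more and none was lower, with a score of 1.26 ± 1.13 against 0.64 ± 1.24, a difference of 0.62 that is within 1 SD (percentile 100) and was 0.96 after median-ratio scaling. Col1a1 was at 3.34 ± 2.86 against 0.88 ± 1.98 and was found in 18 of 29 mutant cells (62.1%, 42.3 to 79.3) and 3 of 18 cap cells (16.7%, 3.58 to 41.4). Within the E13.5 mutant group, Col1a1 at 1 RPKM was more common in cells without Pax2 at 1 RPKM than in cells with it. This split was made after the values were seen, and interstitial cells in the sort would show it too. Col1a2 was higher by 1.67. Col3a1 was higher by 1.72 as a mean of logarithms, but the log2 ratio of its group mean RPKM was -0.17. Pdgfra was found in 8 of 29 and 1 of 18 cells. In the nephrogenic interstitium list 1 of 12 genes was higher, Fat4 (2.04), and none was lower. The member median was 0.03 (percentile 99.6, random median -0.65). The score difference was 0.15, and was 0.63 after median-ratio scaling and 0.37 without pseudogene-high cells. Foxd1 (0.12) and Meis1 (-0.74) were not higher in the mutant by 1 log2 unit, and Meis1 was found in 17 of 18 cap cells at this age. Beyond Xist (5.13), the named genes with the largest positive differences were Nfib (3.69), Anxa2 (3.42), Olfml3 (3.16), Maged2 (2.72), Erdr1 (2.71), Lpar1 (2.66), Zfp536 (2.54), Dnm3os (2.51) and Col1a1 (2.46). The Erdr1 value is that of the entry labelled with the Y chromosome, of a symbol on more than 1 entry. Sex differed in this comparison, so this value cannot be told apart from sex. Matrix genes had a score difference of -0.17 as deposited and 0.14 after median-ratio scaling, with 1 of 14 higher and 4 lower.

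G2 and M phase genes were lower for 11 of 12 members in the E13.5 mutant (2.92 ± 2.47 against 5.90 ± 1.72, percentile 0) and S phase genes for 8 of 12 (2.87 ± 1.98 against 4.50 ± 1.44, percentile 2.01). These differences of -2.98 and -1.63 were -2.48 and -1.28 after median-ratio scaling, and -1.07 and -0.40 as ratios of group mean RPKM. After Sall1, the most negative named genes were Mrpl12 (-4.39), Eif3d (-4.22), Cdca3 (-4.21), Kif22 (-4.14), Ccnb1 (-4.12), Tubb4b (-4.09), Ube2c (-4.09), Kpna2 (-4.09) and Aurka (-4.09), several of which act in mitosis. FGF response genes were lower for 4 of 10 (score -0.75, percentile 13.9), with Dusp6 at -3.19 and Etv5 at -1.71. The Notch pathway list stood at -0.47 (percentile 0.72). All 12 oxidative phosphorylation genes (score -2.02, percentile 3.17, and -0.65 as a ratio of group mean RPKM) were lower. Glycolysis (score -1.24) and housekeeping genes (score -1.40) differed no more than genes of like expression. Their member medians of -1.447 and -1.265 were at percentiles 25.3 and 64.2, against random medians of -1.25 and -1.38. Both scores stood at -0.61 after median-ratio scaling. Without the cells at 20000 RPKM or more for the ATP synthase pseudogene (21 mutant and 17 cap cells kept), the differences were -1.75 for the progenitor list, 0.63 for the stromal list, -2.62 for G2 and M phase, -0.98 for oxidative phosphorylation, -1.26 for S phase, -0.62 for glycolysis and -0.73 for housekeeping genes. A comparison matched on genes per cell had no value, since 2 cap cells had 3000 to 5000 genes.

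Between the ages, wild-type cap cells differed in cell cycle, oxidative phosphorylation and immediate early genes. G2 and M phase genes were lower at E18.5 for 10 of 12 members (score -2.01, percentile 0, -3.15 to -0.65 over the alternatives). S phase genes were lower for 5 of 12 (-0.81, percentile 7.96, and near 0 as a ratio of group mean RPKM). Immediate early genes were higher for 3 of 12 (score 0.76 higher), led by Egr1 (4.54), which was found in 67 of 74 cells at E18.5 and 3 of 18 at E13.5. Meis1 was lower at E18.5 (-3.97), as were Igf2bp3 (-3.66) and Ccnd2 (-3.25). Cited1 (2.27), Six3 (3.47), Il33 (4.31), Igfbp5 (3.55), Dhrs3 (3.08) and Tnc (2.75) were higher. The progenitor score was 0.37 higher at E18.5 (percentile 99.8) and the FGF score 0.48 higher (percentile 99.3), while oxidative phosphorylation was lower for 11 of 12 genes (-1.53). Cells at 20000 RPKM or more for the ATP synthase pseudogene were 20 of 74 at E18.5 and 1 of 18 at E13.5, which bears on the oxidative phosphorylation value. Its member Atp5b stood at -1.57, with -1.68 to -0.73 over the alternatives. Mutant cells of the same sex at both ages differed more in stromal genes. Of the stromal list 9 of 14 genes were higher at E18.5 and none was lower (score 2.31 higher), and of the matrix list 11 of 14 were higher and none was lower (1.93 higher). Nephrogenic interstitium genes were higher for 7 of 12 (1.27 higher). The S phase (-1.95, -3.05 to -0.99 over the alternatives) and G2 and M phase (-2.12, -3.28 to -1.09) scores were lower at E18.5, and the immediate early score was 1.78 higher. Penk (6.51), Ifitm1 (5.46) and Postn (5.41) were among the 10 genes with the largest positive differences between mutant ages, and Fam60a (-5.08), Hmga2 (-5.01), Sox11 (-4.93) and Nnat (-4.71) had the most negative.

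A lineage index placed each cell between the wild-type lineages by the 100 genes that most favoured each lineage at E18.5. The genes were chosen in 37 cap and 36 interstitium cells, and the scale was set in the other 37 and 35 cells so that cap cells had a median of 0 and interstitium cells of 1. E18.5 mutant cells had a median of 0.918 (quartiles 0.842 and 0.980, range 0.471 to 1.11), and 42 of 44 lay above 0.5 (95.5%, 84.5 to 99.4). The highest held-out cap cell, at 1.01, was exceeded by 9 of 44 mutant cells (20.5%, 9.80 to 35.3), a share that ranged from 3.03 to 36.4% over the alternatives. Held-out cap cells above 0.5 numbered 3 of 37 and held-out interstitium cells at or below 0.5 numbered 6 of 35. These 3 cap cells (0.819, 0.980 and 1.01) had Six2 at 0 and Pdgfra at 3.47, 6.62 and 4.90. The next highest held-out cap cell, at 0.359, lay below the lowest mutant cell. The 9 of 44 thus counts mutant cells past a cap-sort cell with stromal transcripts, and does not place the others among cap cells with Six2. E13.5 cap cells had a median of 0.173 (quartiles 0.0778 and 0.212) and E13.5 mutant cells of 0.3999 (quartiles 0.309 and 0.547), with 9 of 29 mutant cells above 0.5. A cell with none of the index genes would sit at 0.399, so the position of the E13.5 mutant cells cannot be read without the levels. The lowest held-out interstitium cell, at 0.134, lay below that point, and being above it (44 of 44 E18.5 mutant, 29 of 29 E13.5 mutant and 11 of 18 E13.5 cap cells) does not show likeness to interstitium. The mean over interstitium index genes was 2.28 ± 0.93 in E13.5 mutant and 1.90 ± 1.001 in E13.5 cap cells, and the mean over cap index genes was 2.05 ± 0.60 and 2.92 ± 0.71. In E18.5 mutant cells these means were 4.24 ± 0.90 and 1.31 ± 0.33, against 4.62 ± 1.31 and 1.86 ± 0.89 in held-out interstitium cells.

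**Figure D3:**
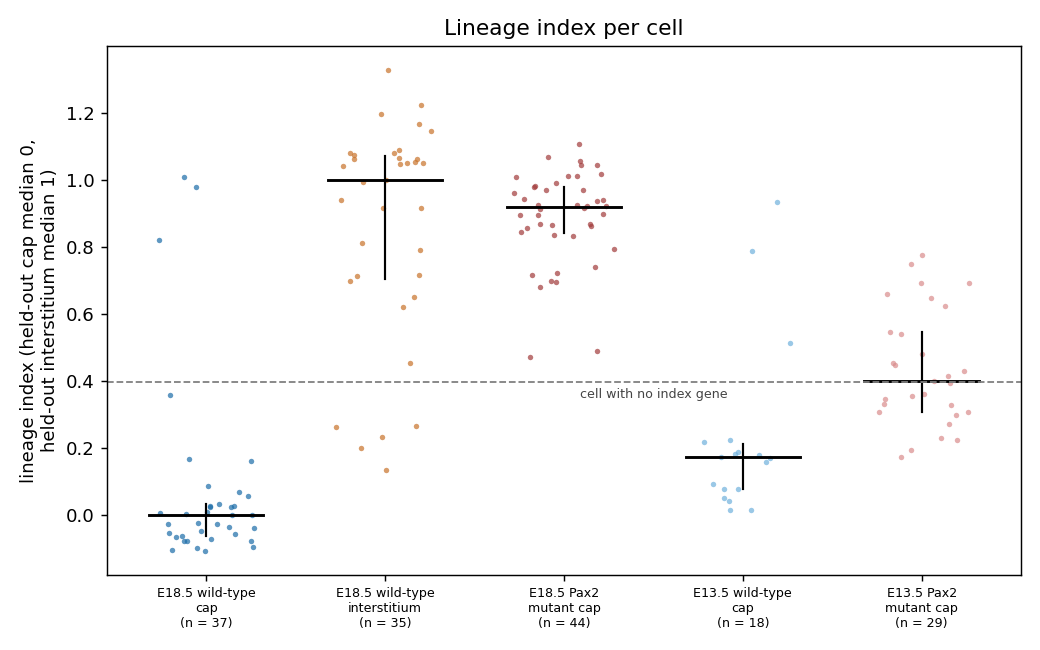
Lineage index (vertical axis, no unit, 0 at the median of held-out E18.5 cap cells and 1 at the median of held-out interstitium cells) by group (horizontal axis). Points are cells, lines are the median and quartiles, and the dashed line at 0.399 marks a cell with no index gene; the E18.5 mutant median is 0.918 and the E13.5 mutant median 0.3999.

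Six2 was looked for together with stromal transcripts in single cells, with both at 1 RPKM or more. Six2 with Col1a1 was found in 7 of 74 E18.5 cap cells (9.46%, 3.89 to 18.52), 17 of 71 interstitium cells (23.9%, 14.6 to 35.5), 1 of 44 E18.5 mutant cells, 2 of 18 E13.5 cap cells and 4 of 29 E13.5 mutant cells (13.8%, 3.89 to 31.7). Independent detection within each group would give 11.7, 17.9, 1, 2.33 and 5.59 cells. Six2 with Col3a1 was found in 6, 16, 1, 1 and 6 cells of these groups, with Pdgfra in 1, 12, 1, 0 and 1, with Foxd1 in 23, 8, 1, 3 and 1, with Meis1 in 26, 18, 1, 14 and 9, and with Tbx18 in 0, 0, 1, 0 and 1. The counts from independent detection were 10.05, 17.9, 1, 1.56 and 5.59 for Col3a1, 6.70, 15.5, 0.932, 0.778 and 2.48 for Pdgfra, 20.95, 10.97, 0.614, 3.11 and 1.55 for Foxd1, 30.2, 18.46, 0.955, 13.2 and 8.07 for Meis1, and 0, 0.268, 0.227, 0.778 and 1.24 for Tbx18. Pdgfra was thus found with Six2 in fewer E18.5 cap cells (1) than independent detection would give (6.70). Tbx18 itself was found in 10 of 44 E18.5 mutant and 0 of 74 E18.5 cap cells. No doublet caller was run on so few cells, so a cell with both transcripts is not told apart from a pair captured together, which would add to these counts. With any value above 0 in place of 1 RPKM, the share with Six2 and Col1a1 was 29.7, 54.9, 56.8, 61.1 and 44.8%.

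Clustering of all labelled cells gave 8 clusters, of which 2 were classed as nephron progenitor-like. These nephron progenitor-like clusters held 52 of 74 E18.5 cap cells (70.3%, 58.5 to 80.3), 11 of 71 interstitium cells (15.5%, 7.996 to 26.03) and 0 of 44 E18.5 mutant cells (up to 8.04%). Over 5 other clusterings the cap count stayed at 52. The interstitium count moved to 18 (25.4%, 15.8 to 37.1) at resolution 1.5, 8 (11.3%, 4.992 to 21) with 3000 variable genes and 10 with Ward clustering, and the mutant count was 1 at resolution 0.5 and 0 otherwise. Without the members of the fixed lists the counts were 52, 11 and 0. The E13.5 shares moved with the settings, from 22.2 to 83.3% of cap cells and from 3.45 to 51.7% of mutant cells, and are not compared. Cluster 1 held 38 of 44 E18.5 mutant, 6 of 71 interstitium and 3 of 74 cap cells, while clusters 7 and 8 held 22 interstitium cells each and no mutant cell of either age. No name was given to the stromal clusters as a class, because the markers that lead cluster 8 include the mural gene Rgs5 and no stromal list member.

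Transcripts of other kidney and blood cell types were low in every group. The mean score was at most 0.88 for the committing nephron list (E13.5 cap), 0.89 for mural and smooth muscle (interstitium), 0.89 for podocyte (E13.5 cap), 0.51 for epithelial adhesion (E13.5 mutant), 0.34 for ureteric epithelium (E13.5 mutant), 0.35 for loop and distal tubule (interstitium), 0.10 for proximal tubule (E18.5 cap), 0.32 for endothelium (E13.5 cap), 0.22 for immune (E18.5 mutant), 0.08 for erythroid (E18.5 cap), 0.39 for neural and glial (E13.5 cap) and 0.63 for skeletal muscle and cartilage genes (E13.5 mutant). Single cells reached a score of 2 or more: 1 E18.5 mutant cell for immune genes (6.64), 2 E13.5 mutant cells for epithelial adhesion (up to 6.99), 1 E13.5 mutant cell for ureteric epithelium (3.15), 1 E13.5 mutant cell for loop and distal tubule (2.07) and 1 E13.5 cap cell for endothelium (4.96). For committing nephron genes 2 interstitium and 1 E13.5 cap cells did so, and for mural genes 2 interstitium, 3 E18.5 mutant and 1 E13.5 mutant cells. Mutant minus cap differences at E18.5 were -0.43 for p53 targets and apoptosis, -0.29 for Wnt targets, -0.28 for the Notch pathway, 0.18 for hedgehog response, 0.02 for the retinoic acid pathway and -0.18 for transcription factors of the epithelial to mesenchymal transition, which turned positive as a ratio of group mean RPKM. As such ratios the p53, Wnt and Notch differences were -0.14, -0.50 and -0.11. The retinoic acid difference was -0.22 without pseudogene-high cells, 0.18 after median-ratio scaling and 0.44 in cells with 3000 to 5000 genes, so its direction is not settled, and the hedgehog difference was 0.09, 0.30 and 0.40. At E13.5 the same differences were -0.21, 0.00 and -0.47 for p53, Wnt and Notch genes and -0.35 for the transition factors. After median-ratio scaling they were -0.04, 0.24, -0.33 and -0.07, and as ratios of group mean RPKM 0.50, 0.41, -1.04 and 0.37, so the direction for p53 and transition factors is not settled. The hedgehog (-0.15) and retinoic acid (-0.19) differences at E13.5 turned positive after median-ratio scaling, and immediate early genes did not differ (0.01). Between interstitium and cap cells, p53 (-0.17), Wnt (-0.12), Notch (-0.15), FGF response (0.11), glycolysis (0.05), housekeeping (0.25) and transition factor (-0.01) scores were close. The sex-linked list, which holds Xist and Y-linked genes, stood at 1.08 for interstitium minus cap, -0.06 and -0.9998 for mutant minus cap at E18.5 and E13.5, and -1.13 for mutant minus interstitium.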

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

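The tests of ordinary interstitial cells in the mutant sort and of the interstitium cells with a progenitor profile were chosen after the results were seen.

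Ifitm1, Nnat, Slc1a3 and Snora81 differed between mutant and cap cells in opposite directions at the 2 ages, by 1 log2 unit or more at each. Ifitm1 was 4.73 higher in the mutant at E18.5 and stood at -1.57 at E13.5, a gap of 6.29. Nnat stood at -2.35 and 1.203 (gap -3.56), Slc1a3 at -2.63 and 1.09 (gap -3.73), and Snora81 at -2.52 and 1.65 (gap -4.17). With the median over cells in place of the mean, the E13.5 difference was 0 for Ifitm1, Slc1a3 and Snora81, so the opposite direction was not seen in the typical cell, while Nnat stayed at 1.37. The difference between ages was not tested, since each group is 1 sample, and mutant and cap cells differ in sex at E13.5 only. The cell with disagreeing labels, which had Y-linked transcripts as E13.5 cap cells do, scored 1.30 for immediate early genes and 4.33 for the Pax and Hox network list, above the highest of the 18 E13.5 cap cells. Its lineage index was 0.110.

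E18.5 mutant cells held stromal transcripts and few progenitor transcripts. In cells with 3000 to 5000 genes (33 mutant and 26 cap), the stromal score difference was still 2.895, with an SD of 1.23. Without cells dominated by the mitochondrial pseudogene (40 and 54 kept) it was 3.03. Undetected genes lower a score, so fewer genes per mutant cell would not raise stromal genes, and the matched value is no real test of this. Few progenitor transcripts are what fewer genes could give. The progenitor difference was smaller in matched cells, so a part of gene number in it stays open. Ordinary interstitial cells in the mutant sort stay open: with the sex-linked list (-1.13) set aside, of 5 lists that separated mutant from interstitium cells by more than 1 SD, 1 did so in matched cells as well (FGF response, -1.58 in all cells and -1.27 in 33 mutant against 35 interstitium cells), which met a bound of 1 list written after the result was seen. It is too few to exclude them, and the day, pool and sex of these groups differ. A change of identity of cap cells without Pax2 is the biological explanation the design names, and it may hold, but it cannot be told apart here from sorting of interstitial cells.

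E13.5 mutant cells lay between cap and interstitium cells on the lineage index. Sex-linked genes in the index could not have raised the mutant cells. Xist was among its cap genes and Ddx3y among its interstitium genes, while the mutant cells held Xist. Leaving these genes out was thus bound to move the mutant median up. Its value of 0.4214, above the upper quartile of 0.211 of E13.5 cap cells, is therefore no test of this explanation. Little RNA per cell stays open for the group median. Without pseudogene-dominated cells this median was 0.4715, above the cap quartile of 0.239, which had been set beforehand as the bound against this explanation. The bound was wrong, because on that scale a cell with no index gene would sit at 0.514. On the main scale that point is 0.399, and little RNA would draw cells toward it and not past it. The 9 of 29 mutant cells above 0.5, up to 0.775, thus argue against little RNA for these cells alone. Of the E13.5 cap cells, 3 of 18 lay above 0.5 too. Loss of cap transcripts with no gain of interstitium transcripts stays open too, since interstitium index genes were higher by 0.6342 (2.11 against 1.48), within the SD of 0.833.

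In the interstitium group 11 cells fell in progenitor-like clusters (8 to 18 over other clusterings), with Pax2 in 11, Six2 in 10 and Col1a1 in 8 of them. Cells carried over from the E18.5 cap sample are argued against, since 0% of the 11 had Xist (up to 28.5%). Interstitium and progenitor cells captured together stay open: the stromal score was 1.372, with an SD of 1.27, against 3.095 in the other 60 interstitium cells and 0.31 in 52 progenitor-like cap cells. In the 50 of the 60 in clusters 1, 7 and 8, which were picked on markers that are part of this list (cluster 8 was given no name), it was 3.01, and the 11 cells had 1.198 times as many genes at the median as these 50. Progenitors that passed the sort as single cells may give the same values.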

How the results depend on the processing

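The 3000 to 5000 gene, pseudogene, sex-linked and list-free clustering tests were chosen after the results were seen. A value counted as within its spread when an alternative shifted it by less than the SD between cells. Shares had to stay in their exact interval. A difference of 1 log2 unit or more that changed sign counted as reversed. Large shifts can thus count as within the spread, such as G2 and M phase for mutant minus cap at E13.5, from -2.98 to -1.07. Of the values for Pax2, 39 alternatives left the value within its spread and 4 moved it. For the leading list scores 229 were within the spread, 10 moved and 1 reversed, for the index 139 and 11, and for leading shares 33 and 12. For named genes 7498 were within the spread, 237 moved and 9 reversed. For the other list scores the numbers were 1882, 72 and 1, and for the other shares 205 and 55. The cause of these changes was not tested, except that a smaller pseudocount widens differences from 0 by construction.

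With a pseudocount of 0.1, Pax2 stood at -3.63 for interstitium minus cap and -5.20 for mutant minus cap at E18.5. The stromal score was 3.69 and 4.51 in these comparisons, the progenitor score -4.05 for mutant minus cap at E18.5 and -2.83 at E13.5, and the S phase score -4.25 for mutant minus interstitium. With 10, Pax2 stood at -0.84, the progenitor score at -1.20 and the stromal score at 1.68 for mutant minus cap, and the stromal score at 1.13 for interstitium minus cap. As a ratio of mean RPKM, Pax2 stood at -1.79 for mutant minus interstitium. In progenitor-like cells alone, interstitium minus cap was 0.54 for the progenitor list (reversed), 0.58 for nephrogenic interstitium and 1.07 for stromal. Such cells were picked on members of the progenitor list, so the reversal does not speak to the lineages as a whole. In cells with 3000 to 5000 genes, oxidative phosphorylation reversed to 0.071 for mutant minus cap at E18.5.

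As ratios of mean RPKM, these genes reversed: Figf for interstitium minus cap (-0.73), Dusp6 for mutant minus cap (0.68) and minus interstitium (0.79) at E18.5, Il33 (0.42) and Wt1 (0.39) for mutant minus interstitium, and Chst2 (0.063), Col3a1 (-0.17) and Dhrs3 (-0.52) for mutant minus cap at E13.5. Igfbp5 for mutant minus interstitium reversed to 0.37 with the median over cells.

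The share of E18.5 mutant cells above the highest cap cell on the index was 6.82% with median-ratio scaling, 4.55% with ratios of means, 6.82% with pool 3 alone, 36.4% with 50 genes, 6.82% with odd and even cells swapped, 9.09% without list members and 3.03% in cells with 3000 to 5000 genes. The share of E13.5 cap cells above the lowest interstitium cell was 83.3% with the median over cells, 22.2% with pool 2 alone, 100% after the swap and 88.2% without pseudogene-dominated cells. Pax2 was found in 85.1% of E18.5 cap cells at any value above 0, 56.8% at 5 RPKM and 85.2% without pseudogene-dominated cells, and in 12.7% of interstitium cells at 5 RPKM.

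Progenitor-like E13.5 cap cells made up 83.3% at resolution 0.5, 72.2% at 1.5, 72.2% with 3000 variable genes, 83.3% with Ward clustering and 77.8% without list members. For E13.5 mutant cells the shares were 51.7% at 0.5, 3.45% at 1.5 and 6.90% with 3000 variable genes. The index medians ranged from 0.885 to 1.01 in E18.5 mutant, 0.247 to 0.485 in E13.5 mutant and 0.109 to 0.219 in E13.5 cap cells.

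No value was possible in progenitor-like cells alone for E18.5 mutants (0 cells) or E13.5 cap cells (4 cells). In cells with 3000 to 5000 genes none was possible for comparisons with E13.5 cap cells (2 cells). Depth is unknown, so a value of 0 limits cells with detected transcript and not cells that express a gene.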

Other observations

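The tests of imprinted genes, and the choice of both lists, were made after the result was seen.

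Several imprinted genes stood among the genes with the largest differences. Meg3 had a mean log2(RPKM + 1) of 5.77 in E18.5 mutant, 2.05 in interstitium and 0.66 in E18.5 cap cells, and Rian of 5.08, 1.71 and 0.52. Cdkn1c was at 9.27, 7.95 and 4.09, while Peg12 was lower in the mutant, at 0.68, 5.31 and 4.57. A hypothesis is that imprinted genes as a class are higher in mutant than in cap cells beyond genes of like expression. Over a list of 23 imprinted genes the median difference was 0.47 (random median -0.36), but that list held the genes that prompted it. Over the 12 members not seen beforehand the median was -0.02, at percentile 91.35 of random lists (random median -0.19), with 2 genes higher and none lower by 1 log2 unit or more. This is short of the percentile set as the limit for the class, so the hypothesis stays open.

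Six3, which lies 58.1 kb from Six2 on chromosome 17 (85613608 to 85626191), was found in 60 of 74 E18.5 cap cells, 56 of which also had Six2. It was found in 0 of 71 interstitium (up to 5.06%), 0 of 44 E18.5 mutant (up to 8.04%), 0 of 18 E13.5 cap (up to 18.53%) and 0 of 29 E13.5 mutant cells (up to 11.9%). Its mean in E18.5 cap cells was 3.47 ± 2.05.

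Zfp536 was found in 17 of 29 E13.5 mutant and 6 of 44 E18.5 mutant cells, and in 0 cells of the wild-type groups.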
